A study of Homo sapiens with 6 samples.

How the data were processed

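Polyadenylated RNA from HK-2 cells was sequenced by the authors from stranded libraries, per the labels' protocols. The labels give 3 libraries from cells with a short hairpin against GLIS1 (shGLIS1) and 3 from cells with the vector, with replicate numbers 1 to 3 in each group. The series' design text instead speaks of mice treated to model ageing, and the sample labels, which all name HK-2, were followed. The library codes in the table begin with HG for shGLIS1 and NG for vector, per the file headers, and the labels do not say what these letters stand for. Nothing in the labels says that the 3 libraries of a group came from separate cultures. The p-values of single genes therefore measure the spread between these libraries, which may be technical.

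The deposited table holds FPKM (fragments scaled by transcript length and by the mapped fragments of the library) for 31429 transcripts in the 6 libraries, per the file headers. The transcript identifiers carry the suffix that GENCODE gives to annotation lifted to GRCh37, and that build is the one named in the submitters' processing notes. Those notes also name FastQC, cutadapt, HISAT2 2.1.0, StringTie 1.3.3 and STAR, without the role of each. Every listed transcript has a mean of at least 0.5001 FPKM in the group where it is higher. The filter behind that bound is not given in the sources used here. FPKM divides by transcript length and library total, so the read depth of each library is unknown and no counting interval can be given. StringTie splits reads among overlapping transcripts of a gene by estimation, so a 0 for a single transcript can be a matter of that split.

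Transcripts were joined to genes through their identifiers in GENCODE release 29, which is on another build and was used for gene names, chromosomes, transcript lengths and overlap of genes on a strand, with no coordinates taken from it. A gene was found for 31310 transcripts (99.6%), and the other 119 were left out of gene tests. The FPKM of the listed transcripts of a gene were summed, giving 11892 genes, of which 7849 had several transcripts. A gene sum therefore covers the listed transcripts only.

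Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, 11121 in all, and 771 were not. Values were taken as log2(FPKM + 1), with a pseudocount of 1. Fold changes are on that scale, which understates the change of genes at low levels. The test was limma 3.58.1 in R 4.3.3, two-sided, with moderated variance following the mean, no covariates, and Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05, and shGLIS1 minus vector is the direction of every difference. Means are given with the SD over 3 libraries. A permutation test of 3 libraries against 3 cannot give a p below 0.1, so single genes were not tested that way.

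Of 43 gene lists for mitochondria, senescence, fibrosis, metabolism, stress, growth signalling, cell cycle, housekeeping and cell types, 40 had at least 5 tested genes. They were tested with limma's camera with a preset correlation between genes of 0.01, two-sided, adjusted over the 40 lists. With that preset, camera's p rests on the many tested genes and does not measure the spread between libraries alone. Other splits of the 6 libraries called 4 to 9 lists, so a small p by this test does not by itself show a group difference. With an estimated correlation camera uses the residual degrees of freedom, 4 with all 6 libraries and 3 without vector replicate 2. Of 1331 list entries, 1103 were in the table. List medians are given relative to the median of all tested genes, which was 0.04 on the log2 scale. Counts of list members are given over all genes tested and adjusted over the list alone.

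These lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named GLIS1, GLIS2, GLIS3 and PPARGC1A in any case. It also took the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among called genes with a mean of at least 5 FPKM, an official symbol and all libraries of a group above those of the other. For each list described it took members with the smallest p, up to 4. For markers of other cell types it took the 2 with the highest level. Some genes named outside it are pointed out where they appear, but others, such as PRIM1, SIN3A, PEX5 and GTF2H3, are not. Some genes that the tests called or the lists hold are counted but not reported here by name. The same rule was also applied to the fit without vector replicate 2, a step chosen after that library was seen to stand apart.

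The alternatives were a replicate block, leaving out each library in turn, pseudocounts of 0.1 and 0.01, no filter, a filter at a mean of 5 FPKM, equal medians, quantile normalization, no variance trend, robust moderation, transcripts in place of gene sums, an estimated correlation in camera, and fry in place of camera. Weights estimated for each library were added after the data were seen. The closing section gives their effect. The code was tested on simulated data of 11121 genes with 100 genes changed 2-fold and 100 changed 4-fold. With the spread of all 6 libraries it called 48% of the 2-fold and 87% of the 4-fold genes, with 8 calls among unchanged genes. With the spread found without vector replicate 2 it called 66% and 77%, with 4 such calls. With no effect it made 0 calls in either case. The simulated errors were independent between genes and had the same spread in every library, unlike these data, so the rates need not hold here. Tables were joined with pandas 2.3.3 in Python 3.11.15 and figures drawn with matplotlib 3.10.9.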

Results

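RNA sequencing compared HK-2 cells carrying a short hairpin RNA against GLIS1 with HK-2 cells carrying the vector, with 3 libraries in each group. HK-2 is an established line of human kidney proximal tubule epithelium, and GLIS1 encodes a zinc finger transcription factor related to the GLI and Krüppel proteins. The series title sets GLIS1 beside senescence of cells, kidney fibrosis and the control of mitochondria by PGC-1α in the ageing kidney. The comparison asks which genes and gene groups differ in HK-2 cells when GLIS1 is targeted. Values were FPKM, so the depth of each library is unknown.

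Vector replicate 2 stood apart from the other 5 libraries. Its listed FPKM summed to 348239, against 280938 to 293760 in the others, and 4319 of its transcripts were at 0, against 1435 to 1769. Across genes, its log2 values correlated with those of the other libraries at r = 0.894 to 0.907, while the other 5 correlated with each other at 0.956 to 0.971. The first principal component, with 54.9% of the variance, set this library against the rest, and the groups parted on the next component, with 15.7%. There this library lay at 2.65, nearer to the shGLIS1 libraries than to the other vector libraries. The main values below keep all 6 libraries, and values without vector replicate 2 are given beside many of them.

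**Figure D1:**
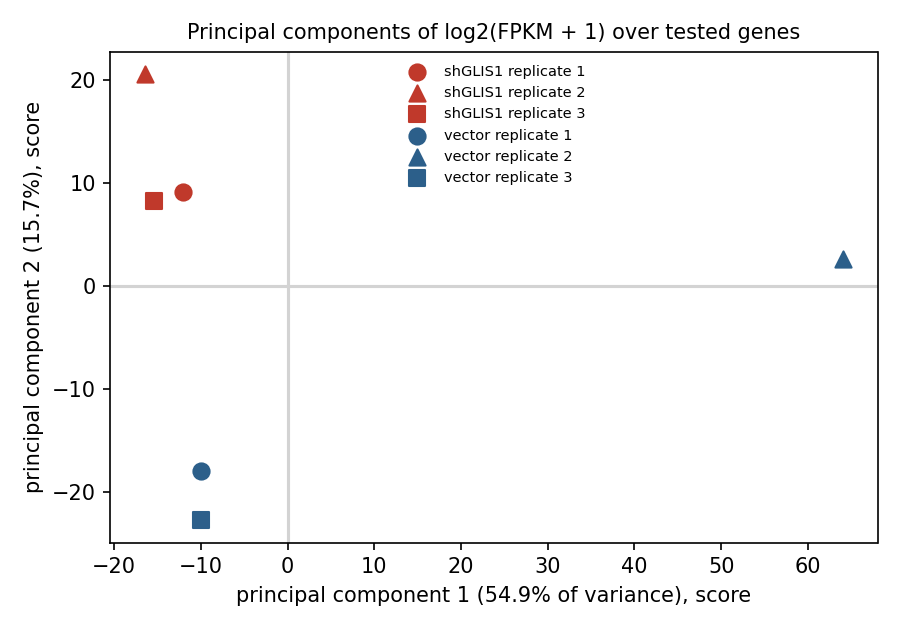
Scores of the 6 libraries on the first 2 principal components of log2(FPKM + 1) over 11121 genes, with colour for group and marker shape for replicate. Vector replicate 2 lies at 64 on component 1 while the other 5 libraries lie between -16.4 and -10. On component 2 the 3 shGLIS1 libraries lie above vector replicates 1 and 3, and vector replicate 2 lies between, at 2.65.

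The level of GLIS1 is not analysed here, because no row used here was matched to it, and so the labels could not be checked on the targeted gene. Its relatives GLIS2 and GLIS3 did not pass the test. GLIS2 stood at 5.68 ± 0.288 FPKM in shGLIS1 and 5.45 ± 0.626 in vector libraries (mean ± SD, n = 3 each), and GLIS3 at 10.1 ± 2.40 and 12.3 ± 1.81, with limma adjusted p of 0.893 and 0.639. PPARGC1A, which encodes PGC-1α, was at 3.20 ± 0.291 FPKM in shGLIS1 and 4.59 ± 0.543 in vector libraries. Its log2 fold change of -0.41 (SE 0.15) did not pass limma's test (adjusted p = 0.495), although all 3 shGLIS1 values lay below all 3 vector values. Without vector replicate 2 the PPARGC1A difference was -0.49 (SE 0.11, adjusted p = 0.162).

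TXNIP, which encodes an arrestin-like protein that binds thioredoxin and is induced by glucose, rose 36.4-fold in shGLIS1 libraries. It stood at 130 ± 12.4 FPKM against 3.57 ± 0.824 in vector libraries (n = 3 each). ARRDC4, a close relative of TXNIP in the same arrestin family, rose from 0.374 ± 0.0593 to 3.24 ± 0.335 FPKM. The zinc finger gene ZMYM1 rose from 0.560 ± 0.327 to 8.16 ± 0.816 FPKM. RINT1, whose product tethers vesicles between the Golgi and the endoplasmic reticulum (ER), fell from 8.67 ± 0.673 to 1.05 ± 0.228 FPKM. For ARRDC4, ZMYM1 and RINT1 only 1 transcript was listed. Their values therefore rest on 1 transcript and may reflect how reads were split among transcripts.

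These genes and AL132780.3 were among the 6 that passed limma's test in all 6 libraries, 5 higher and 1 lower, each at least 2-fold. For TXNIP (ENSG00000265972, chromosome 1) the log2 fold change was 4.85 (SE 0.17, adjusted p = 0.000604). It was -2.25 (SE 0.15, adjusted p = 0.0182) for RINT1 (ENSG00000135249, chromosome 7) and 2.57 (SE 0.20, adjusted p = 0.0258) for ZMYM1 (ENSG00000197056, chromosome 1). ARRDC4 (ENSG00000140450, chromosome 15) had 1.62 (SE 0.14, adjusted p = 0.0384). AL132780.3 (ENSG00000259132, chromosome 14) was listed at 0 in all 3 vector libraries and at 6.92, 13.9 and 6.19 FPKM in the shGLIS1 libraries (limma adjusted p = 0.0384). It also had 1 listed transcript and overlaps AJUBA and HAUS4 on the same strand, so its reads are uncertain. The naming rule took TXNIP, while RINT1, ZMYM1, ARRDC4 and AL132780.3 were named after their values were seen. An unadjusted p under 0.05 was found for 1044 genes (554 higher, 490 lower), and for 1833 (1001 higher, 832 lower) without vector replicate 2, where chance gives 556.1. The groups did not overlap at 2422 genes (21.8%), where chance gives 10%. Both chance values are averages. Genes vary together between libraries, so 1 grouping can lie well above them without a group effect. Other splits were not counted in these ways.

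TXNIP passed in all 16 alternative settings, with adjusted p from 1.65e-05 to 0.0164. RINT1 passed in 9 of 15 (0.00222 to 0.293), ZMYM1 in 7 of 15 (0.00222 to 0.293), ARRDC4 in 6 of 15 (0.00499 to 0.528) and AL132780.3 in 6 of 15 (0.00735 to 0.293), each with its direction kept. The split of calls was 3 higher and 1 lower with equal medians, and 2 higher and 2 lower with quantile normalization. Leaving out any library other than vector replicate 2 gave 1 or 2 calls, and 1 of the 2 without vector replicate 3 was not among the 6 genes.

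**Figure D2:**
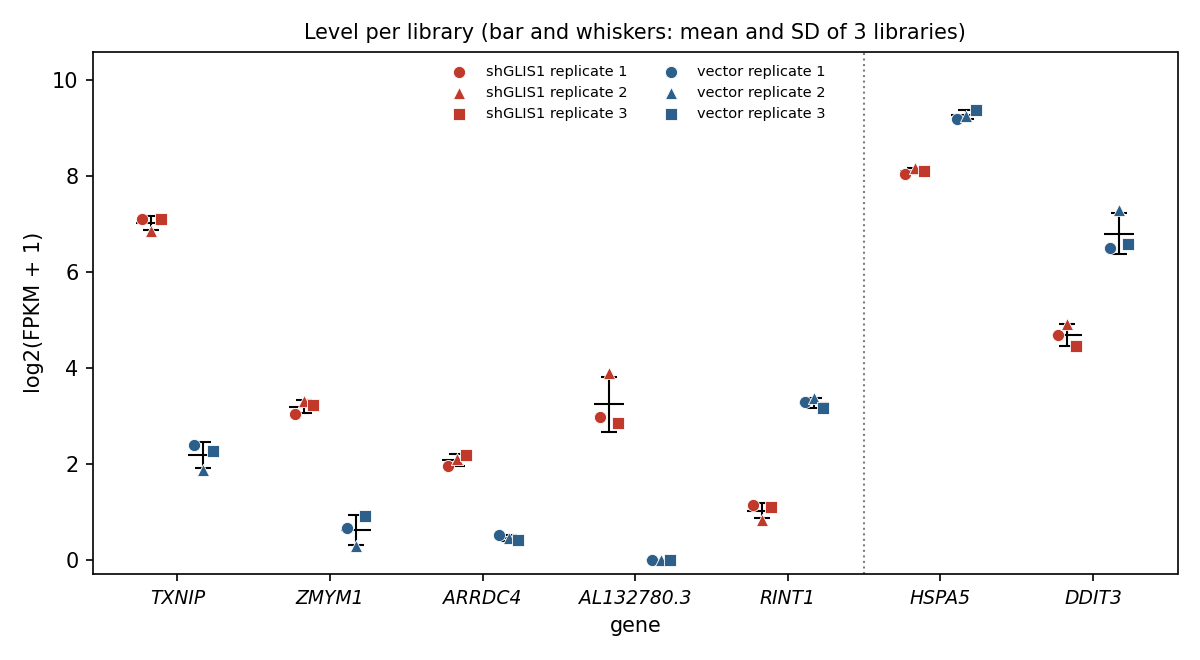
Level of 7 genes in each library on the axis log2(FPKM + 1), with 1 point per library and the mean and SD of 3 libraries per group. Left of the dotted line are 5 of the 6 genes called by limma in all 6 libraries, such as TXNIP at 130 against 3.57 FPKM, and right of it 2 genes of the unfolded protein response, HSPA5 and DDIT3, that were called without vector replicate 2 but not in all 6 libraries.

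Without vector replicate 2, limma called 35 genes, 15 higher and 20 lower, of which 22 changed at least 2-fold. This set holds 5 of the 6 genes called in all 6 libraries, and AL132780.3 had an adjusted p of 0.0544. Among the genes lower in shGLIS1 were 3 of the unfolded protein response list, HSPA5, DDIT3 and SDF2L1. HSPA5, the main ER chaperone, stood at 275 ± 12.02 FPKM against 622 ± 42.4 in all 6 libraries, and its log2 fold change was -1.19 (SE 0.09, adjusted p = 0.0341) without vector replicate 2 and -1.17 (SE 0.14, adjusted p = 0.0851) with it. DDIT3, the stress-induced transcription factor CHOP, stood at 25.03 ± 4.21 against 114 ± 36.2 FPKM, with -1.86 (SE 0.15, adjusted p = 0.0359) without that library and -2.11 (SE 0.24, adjusted p = 0.0851) with it. DDIT3 overlaps AC022506.1 on the same strand. SDF2L1 had a log2 fold change of -1.33 (adjusted p = 0.0214), and the oxidase gene ERO1B, outside that list, -0.95 (adjusted p = 0.0484).

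The same fit called COL8A1, a chain of type VIII collagen, higher by 0.85 on the log2 scale (SE 0.06, adjusted p = 0.0328), and COLGALT1, which glycosylates collagen, by 0.76 (adjusted p = 0.0438). OGA, which removes O-linked N-acetylglucosamine from proteins, was higher by 0.87 (adjusted p = 0.0341), TMEM44 by 1.10 (adjusted p = 0.0424) and the homeobox gene ADNP by 1.34 (adjusted p = 0.0341, and 0.0512 in all 6 libraries). Lower were GPNMB, by a log2 fold change of -1.44, the matrix protein gene CCN3, by -1.19, and ZNF584, by -1.12, along with the kinase gene ITPKA and the hexokinase-like gene HKDC1 (adjusted p = 0.0484 and 0.0448). G3BP1, SLN, SH3BP2 and RAB31 had log2 fold changes of 2.00, 1.91, 1.86 and -1.29. Their calls rest on setting aside vector replicate 2, as do those of the other genes named for this fit apart from TXNIP. With all 6 libraries limma's adjusted p was, for example, 0.606 for G3BP1, 0.426 for GPNMB and ZNF584, 0.396 for HKDC1 and 0.0834 for CCN3. G3BP1 was at 45.1 ± 1.76 FPKM in shGLIS1 libraries, at 10.8 and 10.4 in vector replicates 1 and 3, and at 72.7 in vector replicate 2. SLN was likewise at 43.8 FPKM and RAB31 at 5.86 in that library, beyond the shGLIS1 values, and SH3BP2 at 10.8, between the groups. GPNMB, at 21.85 FPKM, and ZNF584, at 4.86, also lay between the groups there. Of the 35 genes, 31 had groups that did not overlap in all 6 libraries, against 21.8% of all tested genes. They were called from these same libraries less vector replicate 2, so the count bears only on that library's position. Apart from TXNIP, the genes named here for this fit passed in 2 of the 16 alternatives, this fit and the added one with library weights, and DDIT3 also with quantile normalization. Their highest adjusted p over the alternatives lay between 0.446 and 0.848.

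Genes of the unfolded protein response and ATF4 targets, which act on misfolded protein in the ER and on amino acid stress, fell as a list in shGLIS1 libraries. Of 37 tested members, 29 had negative log2 fold changes, with a median of -0.41 relative to all genes (camera adjusted p = 1.37e-11, and adjusted p = 0.0746 with an estimated correlation). The estimate was 0.0098, near the preset 0.01, so a higher correlation does not account for the larger p. That p was taken on the 4 residual degrees of freedom. In limma, 0 members passed over all genes tested, 14 were lower adjusted over the list alone, and 18 were lower at an unadjusted p under 0.05. DNAJB9 stood at 6.05 ± 0.295 against 15.3 ± 2.14 FPKM (log2 fold change -1.20, SE 0.15, adjusted p = 0.104), and MANF at 24.1 ± 8.69 against 91.0 ± 22.4 FPKM (-1.91, SE 0.30, adjusted p = 0.188). Without vector replicate 2, 32 of 37 members were negative (camera adjusted p = 7.22e-14, and adjusted p = 0.261 with an estimated correlation). In that fit 3 members fell over all genes tested, and 22 adjusted over the list alone. The camera adjusted p lay between 5.83e-15 and 6.41e-08 over the 16 alternatives.

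DNA replication genes rose as a list, with 41 of 43 members positive and a median of 0.31 relative to all genes (camera adjusted p = 5.14e-08, and adjusted p = 0.0889 with an estimated correlation). That correlation was estimated at 0.011, again near the preset 0.01. The clamp loader gene RFC3 stood at 26.1 ± 0.671 against 18.8 ± 0.995 FPKM, and UHRF1 at 51.0 ± 4.10 against 34.8 ± 3.82. In limma 0 of the 43 passed over all genes tested or adjusted over the list alone, and 11 were higher and 1 lower at an unadjusted p under 0.05 (23 and 1 without vector replicate 2). Without vector replicate 2, 16 members rose and PRIM1 fell adjusted over the list alone (camera adjusted p = 1.75e-10, and adjusted p = 0.261 with an estimated correlation). Mitotic genes of the proliferation list also rose together, with 30 of 33 positive and a median of 0.26 (camera adjusted p = 1.11e-05, and adjusted p = 0.266 with an estimated correlation). BIRC5 was at 17.8 ± 3.95 against 10.2 ± 0.255 FPKM and CCNA2 at 51.5 ± 2.21 against 38.8 ± 0.574. In limma 0 of the 33 passed over all genes tested or adjusted over the list alone, 6 were higher at an unadjusted p under 0.05 (12 without vector replicate 2), and 5 were higher adjusted over the list alone without that library.

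Heat shock genes rose as a list, with 17 of 18 positive and a median of 0.22 (camera adjusted p = 0.00488, and adjusted p = 0.266 with an estimated correlation). HSPA1A stood at 71.8 ± 7.16 against 50.2 ± 1.24 FPKM, but it is nearly identical to HSPA1B and reads of the pair are uncertain. The small chaperone gene CRYAB went the other way, at 16.8 ± 1.91 against 24.8 ± 2.85 FPKM. In limma 0 of the 18 passed over all genes tested, and 3 were higher and 1 lower at an unadjusted p under 0.05, against 7 and 1 without vector replicate 2. Adjusted over the list alone, 0 members passed with all 6 libraries, and 4 rose and 1 fell without that library. These 4 lists passed camera with all 6 libraries and without vector replicate 2, where heat shock had an adjusted p of 0.00468 and proliferation 3.02e-06. With an estimated correlation 0 of 40 lists passed in either case, where an unadjusted p under 0.05 was found for 6 and 3 lists. By fry, which does not compare a list with other genes, 7 lists passed with all 6 libraries, these 4 with cholesterol synthesis, hypoxia and glycolysis. Without vector replicate 2 fry passed 4, the unfolded protein response, DNA replication, cholesterol synthesis and matrix glycoproteins, while proliferation and heat shock had an adjusted p of 0.0709 each.

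**Figure D3:**
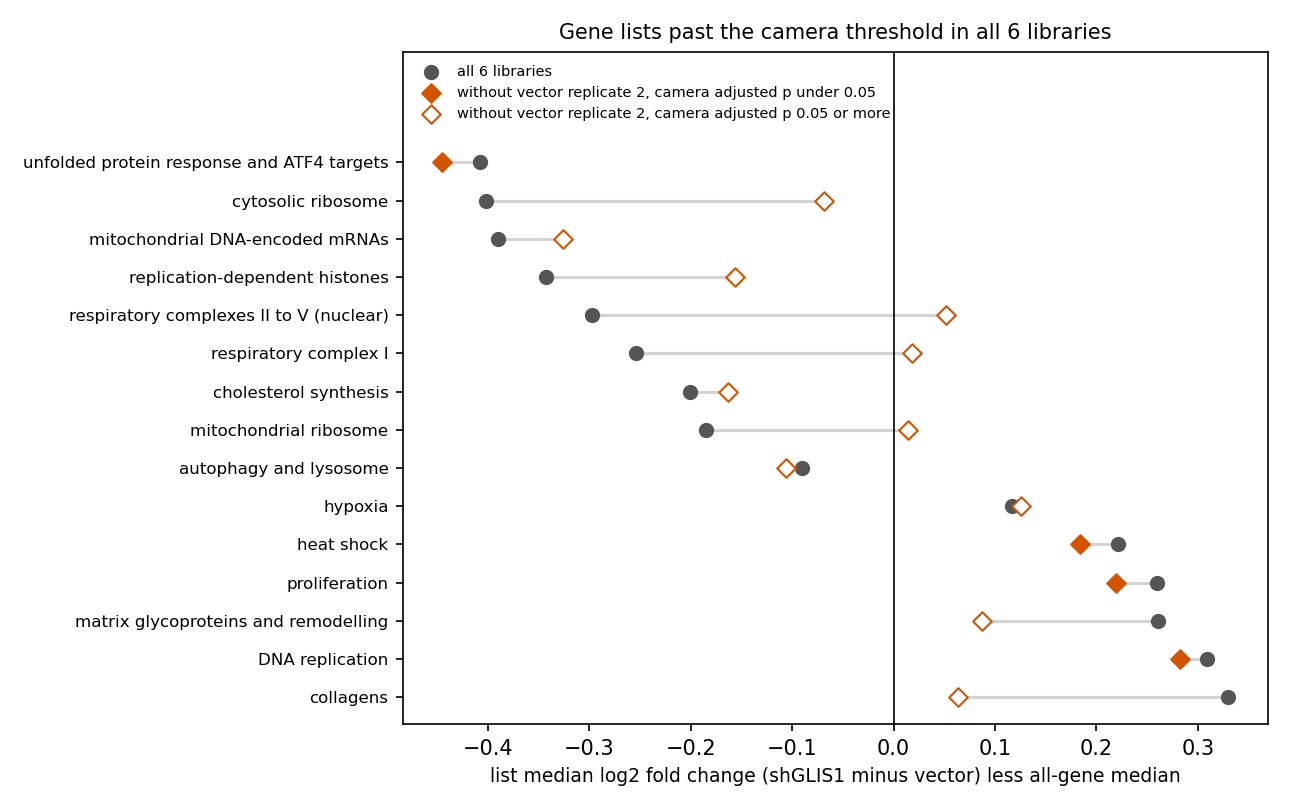
Median log2 fold change of each of the 15 lists past the camera threshold in all 6 libraries, less the median of all genes, with circles for all 6 libraries and diamonds for the fit without vector replicate 2. Filled diamonds mark the 4 lists that also passed without that library, and the unfolded protein response list lies at -0.41 and -0.45.

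Ribosomal protein and respiratory chain genes were lower as lists in all 6 libraries but not once vector replicate 2 was left out. For the 74 cytosolic ribosomal protein genes the median was -0.40 relative to all genes (camera adjusted p = 5.54e-10) with all 6 libraries and -0.07 (adjusted p = 0.111) without that library. With an estimated correlation the adjusted p with all 6 libraries was 0.698 for this list and the 4 mitochondrial lists below, and 0.61 for histones. The estimates were 0.8 for this list, 0.47 to 0.62 for those 4 and 0.27 for histones. RPL5 was at 964 FPKM in vector replicate 2, against 536 ± 11.9 in shGLIS1 libraries. The mitochondrial ribosome list went from -0.18 (adjusted p = 0.000394) to 0.01 (0.688), complex I from -0.25 (0.00301) to 0.02 (0.588) and nuclear genes of complexes II to V from -0.30 (0.00188) to 0.05 (0.378). The 13 mRNAs of mitochondrial DNA went from -0.39 (0.00976) to -0.33 (0.111), and replication-dependent histones from -0.34 (0.0167) to -0.16 (0.43). These 2 lists also missed the threshold without shGLIS1 replicate 2, at -0.07 (0.572) and -0.21 (0.115), and the first with quantile normalization, at -0.04 (0.971). Of 20 histone genes only 8 were tested, with a median transcript length of 650.5 bases against 2834 for all genes. Their median deviation in vector replicate 2 from the other vector libraries was 0.545. In limma, 0 members of these 6 lists passed over all genes tested. At an unadjusted p under 0.05, 4 members were higher and 10 lower, against 17 and 13 without vector replicate 2. The mitochondrial share of listed FPKM was 4.94% in shGLIS1 replicate 2 and 7.93% to 9.42% in the other libraries.

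Among lists tied to fibrosis, matrix glycoproteins (median 0.26, camera adjusted p = 0.00265) and collagens (0.33, 0.0167) were higher as lists in all 6 libraries. Neither passed without vector replicate 2, where the medians were 0.09 (0.103) and 0.06 (0.326), nor with an estimated correlation (adjusted p = 0.698 with an estimated correlation for each). Collagens also missed the threshold without shGLIS1 replicate 2 (0.13). The median transcript length was 4072 bases for matrix glycoproteins and 5709 for collagens, against 2834 for all genes. In vector replicate 2 their median deviations from the other vector libraries were -0.466 and -0.563. Of the 10 splits of the 6 libraries, 6 gave collagens a camera p as small as the real one, and 1, the real split, did so for matrix glycoproteins. THBS1, a matrix protein that activates TGF-beta, was at 98.5 ± 1.13 against 58.0 ± 8.56 FPKM (limma log2 fold change 0.76, SE 0.15, adjusted p = 0.281 in all 6 libraries and 0.0477 without vector replicate 2). COL8A1 was at 74.5 ± 0.692 against 38.7 ± 3.71 FPKM. The rise of this sum rests on 1 transcript, ENST00000273342.8_1, at 45.9, 49.9 and 43.9 against 1.43, 0.769 and 1.80 FPKM. Its other listed transcripts were together lower in shGLIS1 libraries, so the rise may reflect how reads were split. Adjusted over the list alone, LOXL1 and THBS1 rose and CCN3 fell among 43 matrix genes, and COL8A1 rose among 16 collagens. The same counts without vector replicate 2 were 7 higher and 2 lower for matrix genes and 1 and 1 for collagens. The TGF-beta response list did not pass (camera adjusted p = 0.8). In it 1 of 25 members rose over all genes tested and 2 adjusted over the list alone, among these SMAD3, at 32.9 ± 2.35 against 17.1 ± 4.43 FPKM. The list still did not pass without vector replicate 2 (0.454), with 6 members higher and 3 lower adjusted over the list alone. Mesenchymal genes (0.243) and epithelial genes (0.787) did not pass as lists. Within them, adjusted over the list alone, SNAI2 fell from 4.02 ± 0.266 to 1.81 ± 0.243 FPKM and CLDN1 from 164 ± 3.12 to 94.4 ± 5.70 FPKM. The lists had 0.32 and 0.826 without vector replicate 2, where CLDN1 also fell over all genes tested (adjusted p = 0.0484). Adjusted over the list alone, 3 mesenchymal genes rose and 1 fell in that fit, against 0 and 1 with all 6 libraries.

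Cell cycle inhibitors and senescence effectors did not pass as a list (camera adjusted p = 0.102, direction down), and its members went both ways. The list passed in 1 of 16 alternatives, without vector replicate 3 (0.0177), and had 0.43 without vector replicate 2, with medians of -0.12 and -0.15 against -0.05 in all 6 libraries. Of 21 members, 1 rose over all genes tested. Adjusted over the list alone, 1 rose and 4 fell, among these GDF15 and the cyclin-dependent kinase inhibitor genes CDKN1C and CDKN1A. The same counts were 4 and 5 without vector replicate 2. GDF15 was at 26.9 ± 2.29 against 57.8 ± 15.5 FPKM and CDKN1A at 16.6 ± 1.96 against 24.5 ± 3.10. Their limma adjusted p over all genes were 0.283 and 0.426. CDKN2A, named outside the rule, was at 105 ± 14.02 FPKM in shGLIS1 libraries and 73.8, 164.9 and 77.8 FPKM in vector libraries. Without vector replicate 2, the library at 164.9, it rose adjusted over the list alone (log2 fold change 0.46, adjusted p = 0.0368, and 0.206 over all genes). Secretory phenotype factors did not pass either (camera adjusted p = 0.847). For the secretory list camera's direction was down while its log2 fold changes, before subtracting the median of all genes, had a median of 0.09 and a mean of 0.01. Its direction was up without vector replicate 2 (adjusted p = 0.588), where adjusted over the list alone 9 members rose and 6 fell, against 1 and 1 in all 6 libraries.

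Lists for the control of mitochondria did not pass. Camera's adjusted p was 0.787 for mitochondrial biogenesis regulators, 0.847 for mitophagy, 0.847 for fission and fusion and 0.503 for the mitochondrial unfolded protein response. On the same scale the biogenesis list had a median of -0.01 and a mean of 0.03, and the mitophagy list a median of 0.04 with camera's direction down. These medians were -0.02 and -0.04 without vector replicate 2, where the lists also did not pass. SQSTM1, the autophagy receptor p62, was at 110 ± 5.07 against 158 ± 10.8 FPKM, and GABARAPL1 at 47.1 ± 19.0 against 13.8 ± 5.25. Neither passed limma's test (adjusted p = 0.402 and 0.406), and SQSTM1 fell adjusted over the mitophagy list alone without vector replicate 2 (adjusted p = 0.0281). In that fit 1 other member of the list rose adjusted over the list alone. Over the 16 alternatives the camera adjusted p for biogenesis regulators lay between 0.55 and 0.938, and for mitophagy between 0.588 and 0.96.

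Cholesterol synthesis and the autophagy and lysosome list were lower, and the hypoxia list higher, in all 6 libraries (camera adjusted p = 0.00546, 0.0312 and 0.0201). In the same libraries, cholesterol synthesis and autophagy each had adjusted p = 0.266 with an estimated correlation and hypoxia had adjusted p = 0.294. All 3 missed the threshold without vector replicate 2, with adjusted p of 0.0556, 0.0526 and 0.103, while their medians went from -0.20 to -0.16, from -0.09 to -0.11 and from 0.12 to 0.13. The autophagy and lysosome list missed the threshold in 7 of 16 alternatives (adjusted p from 0.011 to 0.215), among them leaving out shGLIS1 replicate 2 (0.0546) or 3 (0.116) and vector replicate 1 (0.0515) or 3 (0.144). SQLE, an early enzyme of sterol synthesis, fell from 76.9 ± 2.08 to 44.9 ± 7.19 FPKM adjusted over the list alone, and the glycolytic regulator gene PFKFB4 rose from 6.92 ± 0.894 to 12.98 ± 1.64 FPKM likewise. The 25 lists that did not pass in all 6 libraries had camera adjusted p from 0.0868 to 0.99.

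Markers of other cell types were few. Of 15 endothelial markers 2 were listed, EGFL7 at 12.98 ± 1.25 against 15.0 ± 6.93 FPKM and ENG at 5.04 ± 0.286 against 3.68 ± 0.752. Of 22 immune markers 5 were listed, led by CD74 at 63.6 ± 0.306 against 59.9 ± 11.9 FPKM and CD68 at 20.7 ± 5.94 against 23.4 ± 4.19. Of 26 markers of other nephron segments 2 were listed, CLDN16 at 12.7 ± 1.37 against 19.8 ± 1.60 FPKM and SCNN1A at 11.1 ± 2.99 against 15.4 ± 3.79. Of 18 fibroblast and pericyte markers 6 were listed, led by MCAM at 86.7 ± 13.96 against 72.9 ± 3.79 FPKM. RGS5, at 32.3 ± 4.46 against 69.7 ± 18.9, fell adjusted over the list alone. None of these passed limma's test over all genes. Of 34 proximal tubule markers 7 were tested, and MIOX (12.9 ± 0.997 against 23.7 ± 4.16 FPKM) and ASS1 (36.7 ± 1.99 against 49.7 ± 3.22 FPKM) fell adjusted over the list alone. The proximal tubule list had a median of 0.16, before subtracting that of all genes, with camera's direction down (adjusted p = 0.507), and a median of -0.18 without vector replicate 2 (adjusted p = 0.184). In the latter fit 1 member rose and 2 fell adjusted over the list alone.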

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

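Library weights were the only alternative here chosen after the data were seen; the others were set before. TXNIP passed in all 16 alternatives, and 4 lists (unfolded protein response, DNA replication, proliferation and heat shock) passed camera with the preset correlation in the same 16. Counts of called genes moved. Leaving out each library in turn gave 1 to 35 genes changed, 1 to 15 higher, 0 to 20 lower, 1 to 22 changed at least 2-fold and 4 to 16 lists. The count was 1 without shGLIS1 replicate 1, 2 without replicate 2, 1 without replicate 3, 1 without vector replicate 1, 35 without vector replicate 2 and 2 without vector replicate 3. A pseudocount of 0.1 gave 3 genes changed, 2 higher and 3 at least 2-fold, and one of 0.01 gave 2, 1 and 2. A filter at a mean of 5 FPKM gave 1 changed, 1 higher, 0 lower and 1 at least 2-fold, where 4 of the 6 genes lie below the filter. Equal medians gave 3 higher, and quantile normalization 2 higher and 2 lower. Library weights gave 192 changed, 86 higher, 106 lower, 54 at least 2-fold and 7 lists. Transcripts in place of gene sums gave 23 changed, 15 higher, 8 lower and 23 at least 2-fold. An estimated correlation gave 0 lists and fry 7. The estimated correlation also lowers camera's degrees of freedom. Other than by that and by fewer libraries or genes, the cause was not tested.

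Among the 15 lists called in all 6 libraries, 3 medians changed sign without vector replicate 2. Leaving out each library in turn gave -0.324 to 0.0139 for the mitochondrial ribosome, -0.466 to 0.0179 for complex I and -0.428 to 0.0515 for complexes II to V. With library weights the first was at 0.0113 and the last at 0.0046. With the replicate number as a block, 1 gene was changed (TXNIP, adjusted p = 0.0134), 1 higher, 0 lower and 1 at least 2-fold. The block gave 15 lists, without autophagy and lysosome (adjusted p = 0.0609) and with antioxidant and NRF2 targets (0.0435, against 0.0868 without the block). Deviations of same-numbered libraries from their group means correlated at -0.068, -0.023 and 0.036. The vector mean included the outlying vector replicate 2, so these values cannot tell whether a number marks something shared. GLIS1 gave no value in any setting, replication-dependent histones had too few genes under the filter at 5 FPKM, and lists were not run on transcripts. Depth is unknown in FPKM, so what it limits cannot be stated.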

Other observations

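The tests of vector replicate 2 as the source of list calls, the test of an exchanged label by median position and the other splits for counts of genes were chosen after those results were seen. The comparison of deviations by transcript length and by spread leaves vector replicate 2 out of each reference mean, which was also chosen after a first look.

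Limma on 21154 transcripts called 23, of which 4 belong to genes called in all 6 libraries and 19 to genes not called there, and the fit without vector replicate 2 called 11, of which 6 are among the 23. For SIN3A, a scaffold of histone deacetylase complexes, ENST00000394949.8_1 was at 14.2, 15.5 and 16.0 FPKM in shGLIS1 libraries and listed at 0 in all 3 vector libraries (adjusted p = 0.00906), while the gene sum had adjusted p = 0.553. For the peroxisomal import receptor gene PEX5, ENST00000412720.6_1 was at 8.46, 9.10 and 10.5 FPKM and listed at 0 in all 3 vector libraries (adjusted p = 0.0182). For COL8A1, ENST00000273342.8_1 was at 45.9, 49.9 and 43.9 FPKM against 1.43, 0.769 and 1.80 (adjusted p = 0.00906), while the gene sum had adjusted p = 0.117 and 0.0328 without vector replicate 2. For GTF2H3, ENST00000618160.4_1 was at 15.4, 27.2 and 16.0 FPKM in vector libraries and below 0.05 FPKM in shGLIS1 libraries (adjusted p = 0.0226). Counting transcripts at 0 in every library of a group and at 1 FPKM or more in every library of the other gave 31, of which 27 were at 0 in the vector group. Other splits of the 6 libraries gave 17 to 32.

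Early response genes went both ways. Adjusted over the list alone in limma, FOSL1 rose from 27.1 ± 0.541 to 47.4 ± 8.05 FPKM and DUSP5 fell from 15.1 ± 3.44 to 8.03 ± 0.310 FPKM (n = 3 each), with adjusted p over all genes of 0.285 and 0.368. The list itself did not pass camera (adjusted p = 0.9).

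Vector replicate 2 stands apart from the other libraries. Lower depth as the whole cause is argued against: at 458 long genes of high level its deviations had an SD of 0.681, against 0.211 to 0.289 in the other 5 libraries, 2.86 times their mean. For a label exchanged with a knockdown library the share set earlier did not decide. Only a median position, a measure chosen after the values were seen, argues against it. On principal component 2, vector replicate 2 lay at 2.65. That is nearer to the shGLIS1 libraries (8.23 to 20.6) than to vector replicates 1 and 3 (-17.9 and -22.7). On a scale from 0 at the other vector libraries to 1 at the knockdown mean, it had a median position of 0.0967 over the 35 genes called without it (quartiles -0.164 and 0.614), and 22 of them (62.9%, between bounds of 50% and 75% set earlier) were nearer to vector. Gene length bias may account for part of the difference, since its deviation from the other vector libraries fell with transcript length across genes (Spearman's rho = -0.527, against -0.103 to 0.0611 in the other 5), but genes are not independent replicates and no biological explanation was tested.

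For the lower cytosolic and mitochondrial ribosome, complex I and complexes II to V lists in shGLIS1 libraries, vector replicate 2 alone is a candidate explanation, since 0 of these 4 lists kept an adjusted p under 0.05 by camera without it and their medians then lay between -0.0683 and 0.0515. Their median transcript length was 826.3 to 1285 bases, against 2834 for all genes. Of the 10 splits of the 6 libraries, the real one included, 7 gave a camera p as small as the real one for the cytosolic ribosome list. For the mitochondrial ribosome 10 did, for complex I 10 and for complexes II to V 9, so these calls do not set the real grouping apart. For mRNAs of mitochondrial DNA that library alone is argued against, with a median of -0.39 (quartiles -0.503 and -0.32) with it and -0.326 (-0.406 and -0.237) without it, where the call ended (adjusted p = 0.111) as the SD of t over all genes went from 1.55 to 2.15. That median lay at -0.07 without shGLIS1 replicate 2 and -0.04 with quantile normalization, and 5 of the 10 splits gave this list a camera p as small as the real one. An effect of targeting GLIS1 stays open as untested for all 5 lists.

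TXNIP and ARRDC4 rose while genes of the unfolded protein response fell. Vector replicate 2 alone is argued against as the source, since the list kept a camera adjusted p of 7.22e-14 without it (adjusted p = 0.261 with an estimated correlation, and 0.0746 with all 6 libraries). As a hypothesis, a difference in glucose supply might give this pattern, since TXNIP and ARRDC4 are glucose-induced; 16 other carbohydrate-response targets were higher as a set with all 6 libraries (camera p = 0.00588, 13 positive, p = 0.393 with an estimated correlation). Without that library camera gave 0.188 for the set, a condition added after the first value was seen, so this cannot be told apart from an effect of targeting GLIS1. The labels give 1 growth protocol for both groups but leave the library codes HG (shGLIS1) and NG (vector) unexplained, and GLIS1 itself was not analysed here.

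The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 6 genes and the highest of the others 2, with 1 split reaching the real count. For genes higher the values were 5 and 2 (1 split as large), for genes lower 1 and 2 (5 splits, taking the larger direction of each other split, since which side is which is arbitrary, as also for genes higher), for genes changed at least 2-fold 6 and 2 (1 split) and for lists 15 and 9 (1 split). The smallest camera p for the unfolded protein response list among other splits was 0.00138, against 3.43e-13, and for DNA replication 0.00137, against 3.85e-09.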
